A study of Drosophila melanogaster with 2 samples.

How the data were processed

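Anti-GFP ChIP-seq was measured in 2 biological replicates of whole embryos, mixed sex and 0 to 24 h old, from a line carrying CG9876 fused to GFP at its C terminus. Chromatin was fragmented by sonication, with a size range of 200 to 800 per the labels. The labels number the biological replicates, and both belong to 1 group. Each replicate's list came from its own alignments and a control, the combined list from the alignments of both, and the optimal list from these 3 lists by irreproducible discovery rate (IDR), per the deposited text files. The aligner, the peak caller, their settings and the read depth are not given in the sources used here.

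The deposited lists are in narrowPeak form and exist in dm6 and dm3, per the labels. Column 7 of the deposited lists holds the signal value of each region in the authors' unit, which is used here only to rank, describe and filter regions. Column 9 holds −log10 of a q-value made by the authors. Column 8, where a p-value would stand, held the same placeholder in every region. Within a list, regions were ranked by signal. The q-value was a coarse measure, since 88.0% of reproducible peaks shared the lowest value of the combined list, 2.3e-04. The authors called regions per replicate and on both replicates combined, so the replicate comparison uses the replicate lists. Each replicate list reaches far down, to q-values of 0.81 and 0.75, so that candidates include background by construction.

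Coordinates were written counting from 1. The dm6 genome sequence (RefSeq) and Ensembl release 115 gene models on the same assembly gave 13945 protein-coding genes, 19607 distinct TSSs and 290 tRNA genes on 6 chromosome arms. No coordinates were converted between builds, and annotation was used only with dm6. A summit was assigned to the promoter class when it lay within 1 kb of a protein-coding TSS, and otherwise to 5' UTR, coding exon, 3' UTR, intron or intergenic sequence in that order. Lower-ranked candidates were the 27267 combined regions that overlap no reproducible peak. Random placement put each summit at a uniform position of known sequence on its own arm, 1000 times.

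Gene lists, motifs, tests and alternatives were chosen before the data were examined, except where stated. A gene was called promoter-bound when a reproducible summit lay within 1 kb of any of its TSSs, and each list was compared with all other protein-coding genes by Fisher's exact test (two-sided). Motifs were matched on both strands within 100 bp of the summit and compared with 1 flank per peak, 400 to 600 bp away on a random side, by an exact McNemar test. Comparisons with lower-ranked candidates used Fisher's exact test, also after matching GC content in bins of 2%. Adjustment was by the Benjamini-Hochberg method over 6 classes, 23 lists, 16 motifs or 2080 6-mers, with a threshold of 0.05. Log2 odds ratios had 0.5 added to each cell, with 95% Wald intervals, except that for flanks the ratio of discordant pairs was used. In short lists the added 0.5 shifts the ratio, so that near 0 its sign need not be that of the bound shares. Shares of peaks have 95% Clopper-Pearson intervals. All of these tests run over peaks or genes, which are not independent replicates, so the strongest 2433 regions of each replicate give the spread between replicates as mean ± SD (n = 2).

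Named genes were CG9876 with 5 kb on either side, the genes with the nearest TSS for the 20 strongest reproducible peaks, and up to 4 promoter-bound members of each list with the highest signal. Some list names are older symbols and were matched through RefSeq synonyms, such as phl for Raf and svb for ovo. Delta, nanos and dysf, written Dl, nos and dys in the lists, each matched more than 1 gene through these synonyms and were left out of the tests. Dichaete and ladybird matched no gene as written, and their genes entered the same lists as D, lbe and lbl. Checked after the values were seen, the promoter of nanos was bound (signal 141.7) and those of Delta and dysf were not.

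Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The methods were tested on simulated data. With 2433 random summits the promoter test called 1 of 20 simulations, and with 5% of the summits moved to a TSS it called 20 of 20. Among 13945 genes, a list planted at a log2 odds ratio of 3 was recovered in 20 of 20 simulations with a median of 3.07, with 1 call in 440 tests of the other lists. The simulated genes were bound independently of each other, unlike real neighbouring genes that share a peak. Smaller planted odds ratios were not simulated, so the power to detect them is unknown. A motif planted in 5% of 2433 windows was recovered in 20 of 20 simulations, with 2 calls in 300 tests of the other motifs.

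Alternatives covered a stricter peak list (the 1216 peaks with the higher signal), each replicate alone, promoter windows of 500 bp and 2 kb, whole-peak overlap, other definitions of a shared region, nearest TSS, a logistic model with gene length and TSS number, other backgrounds, other motif windows, and the dm3 lists. Control libraries, reads and coverage tracks were not analysed here.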

Results

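Chromatin immunoprecipitation with an anti-GFP antibody was profiled in whole Drosophila melanogaster embryos of mixed sex, collected from 0 to 24 h of development. The embryos carried a transgene that adds GFP to the C terminus of CG9876, a homeobox gene of the paired-like class, so that the antibody recovers DNA associated with the tagged protein. The series held 1 group with 2 biological replicates and no treatment, and control libraries were not analysed here. For each replicate and for both combined, the authors listed 30000 candidate regions, and from these lists they derived a list of reproducible peaks. The sequencing depth behind the lists is unknown. The comparisons ask where in the genome the tagged protein was recovered, how far the replicates shared those places, and which genes and sequences lie there. All positions are in dm6 unless dm3 is named.

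The reproducible list held 2433 peaks, with a median width of 370 bp. They fell on 2L (472 peaks), 2R (440), 3L (479), 3R (592), X (436) and chromosome 4 (14). Every one of the 2433 was also among the 2433 strongest regions of the combined candidate list, the weakest with a signal of 85.4 and the strongest with 1939.5. On 2R, 1 interval was listed with 2 summits, and both were kept. In dm3 the authors' list held 2382 peaks, a ratio of 1.02 between the builds, with 3 of them in the heterochromatic sequences 3LHet and 3RHet.

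The highest signal in the genome lay at the promoter of CG14100 on 3L (19590445 to 19590798, summit 19590625), with 1939.5 in the combined list, 1184.5 in replicate 1 and 767.6 in replicate 2, rank 1 in each. The next peak, on 2L (480911 to 481274, signal 1652.3), lay in an intron of ush, which encodes a GATA cofactor, at -1403 bp from the transcription start site (TSS) of cbt, a zinc finger transcription factor gene. Promoter peaks followed at Ugalt, a nucleotide sugar transporter gene on X (signal 1375.8), at Lk6, a protein kinase gene on 3R (1283.5), and at px on 2R (1224.4). Among the 20 strongest peaks, 14 had their summit within 1 kb of a TSS. These included Shc, an adaptor of receptor tyrosine kinase signalling (1096.3), mRpL41 of the mitochondrial ribosome (1077), Chro, a chromatin and spindle protein gene (1000.7), and ph-p of the Polycomb group (858.9). CG1888, CG9663, PNPase, CenG1A, Art3 and Smg5 made up the rest, with signals from 828 to 1013.3. The other 6 lay in introns of ush, CG11050 (1118.5) and CG32772 (865.4), or between genes, nearest to CG13323 (989.9), CG4004 (916.9) and hll (848.5). All 20 ranked among the 49 strongest regions of replicate 1 and the 27 strongest of replicate 2.

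The replicates placed their strongest regions at many of the same sites. Of the 2433 strongest regions of replicate 1, 1680 (69.1%, 95% Clopper-Pearson interval 67.2 to 70.9) overlapped the 2433 strongest of replicate 2 by at least 1 bp. Random placement of the replicate 1 regions on the same arms gave 1.25% on average and at most 2.06% in 1000 placements. Intervals on shares of peaks cover counting error only. Of the 2433 reproducible peaks, 1627 (66.9%) were in the strongest 2433 regions of both replicates and 46 in neither. The summit lay in no candidate region of replicate 1 for 55 peaks and of replicate 2 for 16. That does not show an absence of signal, which was not measured outside the listed regions. Across the 2363 peaks matched in both replicates, the rank correlation of signal was 0.57 and Pearson's r of log2 signal was 0.69. These are correlations across peaks, which are not independent replicates. The log2 ratio of the replicates' signals had an SD of 0.61 across peaks.

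Reproducible peaks lay at promoters. In 1615 of 2433 peaks the summit was within 1 kb of a protein-coding TSS (66.4%, 95% Clopper-Pearson interval 64.5 to 68.3), and the strongest 2433 regions of each replicate gave 66.4% ± 0.26 (SD, n = 2). Random placement gave 20.3% ± 0.79 (SD over 1000 placements), so the share was 3.27 times higher (two-sided permutation p = 0.002, the smallest these placements can give). The median distance from summit to TSS was 250 bp, against 2066 bp for the 27267 lower-ranked candidates that overlap no reproducible peak, and 808 summits (33.2%) lay within 100 bp. Lower-ranked candidates were at promoters in 33.6% of cases (log2 odds ratio of reproducible against lower-ranked 1.96, 95% interval 1.84 to 2.09, Fisher exact p = 2.2e-217). The 2433 candidates ranked next after the reproducible peaks were at promoters in 53.3% of cases (log2 odds ratio 0.79, Fisher exact p = 1.2e-20).

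Coding exons showed the opposite, with 10 summits (0.41%) against 10.8% by random placement and 18.8% of lower-ranked candidates (log2 odds ratio -5.74, Fisher exact test, adjusted p = 1.1e-189). The strongest regions of the replicates gave 0.92% ± 0.67 (SD, n = 2) in coding exons. Introns held 21.0% of reproducible summits against 36.4% by random placement, intergenic sequence 11.4% against 28.1%, and 3' UTRs 0.74% against 3.88% (Benjamini-Hochberg adjusted permutation p = 0.0024 for each of these, coding exons and promoters). In 5' UTRs outside the promoter window there were 3 summits (0.12%) against 0.46% (adjusted permutation p = 0.012). The 5' UTR call was lost in the more strongly bound peaks, in replicate 1 alone and with a 500 bp promoter window (adjusted permutation p = 0.058, 0.05 and 0.56, from 0.006 to 0.56 over 5 alternatives). The 5' UTR shares in these settings were 0.08% against 0.47% by random placement, 0.21% against 0.46% and 0.66% against 0.78%. Against the next-ranked candidates, promoters, coding exons and introns still differed and the other 3 classes did not pass the test. For these 3 the log2 odds ratio was -1.59 in 5' UTRs, -0.82 in 3' UTRs and -0.12 in intergenic sequence. Against all lower-ranked candidates it was -2.42, -0.98 and -0.68.

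**Figure D1:**
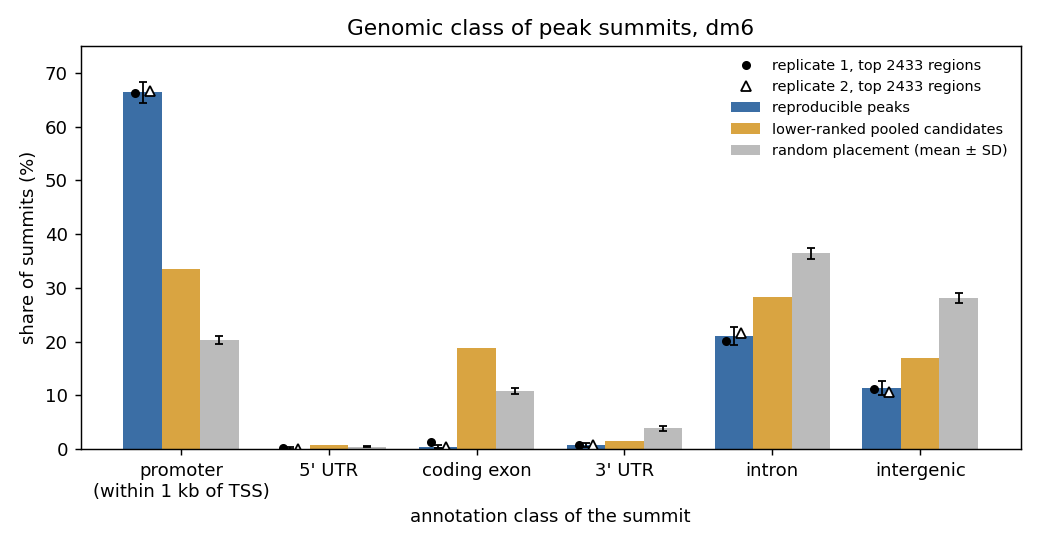
Share of summits (%, y axis) in each annotation class (x axis) for reproducible peaks (blue, with 95% Clopper-Pearson intervals), lower-ranked combined candidates (yellow) and random placement (grey, mean and SD over 1000 placements). Points mark the strongest 2433 regions of each replicate. Promoters hold 66.4% of reproducible summits, and coding exons 0.41%.

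Promoter peaks were somewhat higher than distal ones in the combined list. The median signal was 133 over the 1615 promoter peaks and 120.9 over the 818 others, a difference of 12.1 (permutation test with 100000 resamples, two-sided p = 1.1e-04), against interquartile ranges of 88.1 and 68.0. The difference rested on replicate 1, where the medians were 70.6 and 60.6 (difference 9.99, permutation p = 1e-05, the smallest the resamples can give). In replicate 2 they were 64.8 and 64.3 (difference 0.48, permutation p = 0.72).

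The X chromosome, present at lower copy number than the autosomes in a mixed-sex population, carried 18.5 reproducible peaks per Mb, and 2L, 2R, 3L and 3R together carried 18.2 per Mb, a ratio of 1.02. X held 436 of the 2419 peaks on these 5 arms (18.0%, 95% interval 16.5 to 19.6) against 17.8% of their length (exact binomial p = 0.73). Each replicate alone departed from this share, in opposite directions. X held 19.6% of the strongest regions of replicate 1 (exact binomial p = 0.018) and 16.1% of those of replicate 2 (p = 0.033), and the counts of 476 and 390 in 2433 regions differed between the replicates (Fisher exact p = 0.0014). Lower-ranked candidates lay on X in fewer cases than reproducible peaks (log2 odds ratio 0.34, Fisher exact p = 4.3e-05), but the next-ranked 2433 did not pass that test (log2 odds ratio 0.07, p = 0.52).

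A summit within 1 kb of a TSS marked 2199 of 13945 protein-coding genes (15.8%) as promoter-bound. The strongest regions of the replicates marked 2200 and 2139 genes, of which 1639 were shared. Genes of the cytosolic ribosome stood out. Of 93 ribosomal protein genes, 71 were promoter-bound (76.3%) against 15.4% of other genes (log2 odds ratio 4.13, 95% interval 3.44 to 4.82, Fisher exact test with Benjamini-Hochberg adjustment over 23 lists, adjusted p = 3.2e-37). The strongest regions of the replicates gave 70.4% ± 3.80 (SD, n = 2) for this list. The highest signals were at RpS27 on 3R (25247380 to 25247685, signal 802.9, summit 13 bp from the TSS), RpL7 on 2L (706.4, 29 bp), RpL23A on 3L (639, 102 bp) and RpL34b on 3R (453, 45 bp). Over 8 alternatives the log2 odds ratio ran from 3.445 to 4.33, the latter with gene length and number of TSSs in a logistic model.

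Chemoreceptor genes, which act mainly in sensory neurons, were rarely bound. Of 179 members 2 were bound (1.12%), Or9a (signal 116.9) and Or88a (105.9), for a log2 odds ratio of -3.75 (95% interval -5.56 to -1.95, Fisher exact test, adjusted p = 4.0e-10) and a replicate mean of 0.84% ± 0.40 (SD, n = 2). Over 8 alternatives the log2 odds ratio ran from -5.84, with a 500 bp window, to -2.60. Proteasome genes, which like ribosomal protein genes are used in every cell, were bound in 5 of 34 cases (14.7%) against 15.8% of other genes (log2 odds ratio -0.01, 95% interval -1.32 to 1.31, Fisher exact test, adjusted p = 1). The bound members were led by Rpn5 (178.7), Rpn3 (153.7), Prosbeta1 (142.6) and Rpn6 (100.2). Heat shock genes were bound in 5 of 21 cases (log2 odds ratio 0.83, Fisher exact test, adjusted p = 0.92), with Hsp83 (267.9), Hsp26 (181.3), Hsc70-4 (152.7) and Hsp27 (136.1) highest. Digestive protease and chorion genes were bound in 2 of 35 cases (log2 odds ratio -1.33, Fisher exact test, adjusted p = 0.62). These were Jon65Ai (112.3), a digestive protease gene, and Cp190 (156.7), an insulator protein gene. The symbol pattern had matched Cp190 and Cp110, which are not chorion genes, and without these 2, an alternative chosen after the data were seen, 1 of 33 was bound (3.03%, log2 odds ratio -2.02, 95% interval -4.39 to 0.34, Fisher exact test, adjusted p = 0.39, from 0.151 to 0.901 over 9 alternatives).

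Among signalling pathways, the Notch and EGFR lists had the highest bound shares without passing the test. Notch genes were bound in 7 of 23 cases (30.4%, log2 odds ratio 1.28, Fisher exact test, adjusted p = 0.57), with E(spl)m3-HLH (141.5), the receptor gene N (134.9), Brd (101.3) and E(spl)malpha-BFM (95.2) highest. EGFR and FGF genes were bound in 7 of 25 cases (28%, log2 odds ratio 1.12, Fisher exact test, adjusted p = 0.57), with the ligand genes spi (358.1) and Krn (182.6) and the kinase cascade genes Raf (244.5) and Ras85D (199.4). When each peak was given to its nearest TSS at any distance, both lists passed the Fisher exact test, with log2 odds ratios of 2.00 (adjusted p = 0.016, up to 1 over 8 alternatives) and 2.05 (adjusted p = 0.01, up to 0.884). Other alternatives lowered them, Notch to 0.30 in the more strongly bound peaks (2 of 23) and 0.79 among genes with any candidate, and EGFR and FGF genes to 0.48 among genes with any candidate and 0.35 in the logistic model. BMP genes were bound in 3 of 19 cases (log2 odds ratio 0.18), Mad (358.8), brk (164.8) and wit (90.2). Wnt genes were bound in 2 of 23 (-0.69), sgg (278.9) and nkd (100), and Hedgehog genes in 1 of 11 (-0.39), smo (104.9), with adjusted p = 1, 0.95 and 1 by Fisher's exact test. Without replicate 1, BMP genes were bound in 6 of 19 cases (log2 odds ratio 1.41) and Wnt genes in 5 of 23 (0.72), and BMP genes in 0 of 19 with a 500 bp window (-2.62) and 7 with a 2 kb window (1.33). With the nearest TSS the values were 1.56, 1.18 and 0.68 for BMP, Wnt and Hedgehog genes, and no alternative run on reproducible peaks or on 1 replicate took these 3 lists past the test.

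No list of developmental regulators or differentiation genes passed the test. Hox genes were bound in 0 of 8 cases (log2 odds ratio -1.67, 95% interval -5.79 to 2.44, Fisher exact test, adjusted p = 0.95). Of the 27 genes in the PRD-class list, 4 were bound (log2 odds ratio 0.03, Fisher exact test, adjusted p = 1), namely ey (94.6), eyg (90.8), Ptx1 (90.7) and PHDP (85.8). The 0.5 added to each cell put this ratio above 0, since the bound share was slightly below that of other genes. The ey peak, on chromosome 4, lay in a listed region of replicate 2 only, and the PHDP peak in a listed region of replicate 1 only. The strongest regions of the replicates bound 3.70% and 7.41% of this list. Segmentation genes were bound in 2 of 29 (bcd 181.4, bowl 180), dorsoventral patterning genes in 3 of 26 (ush 200, brk 164.8, pnr 87.3), and mesoderm and muscle identity genes in 2 of 29 (org-1 97.6, pnr 87.3). Their log2 odds ratios were -1.04, -0.33 and -1.04 (Fisher exact test, adjusted p = 0.87, 1 and 0.87). Neural fate genes were bound in 3 of 29 (numb 200.3, brat 192, scrt 90), neuronal differentiation genes in 1 of 23 (elav 249.4) and glial genes in 2 of 15 (moody 420.4, Gs2 202.2), with log2 odds ratios of -0.50, -1.49 and -0.02 (Fisher exact test, adjusted p = 0.95, 0.62 and 1). Muscle structural genes were bound in 2 of 24 (Msp300 593.6, sls 223.3, log2 odds ratio -0.75, Fisher exact test, adjusted p = 0.95), tracheal genes in 1 of 15 (bnl 127.2, -0.86, adjusted p = 0.95) and endoderm and gut genes in 3 of 15 (bowl 180, fkh 152.9, cnc 135.6, 0.58, adjusted p = 1). Hemocyte genes were bound in 2 of 15 (ush 200, Hml 94.5, -0.02, Fisher exact test, adjusted p = 1) and epidermis and cuticle genes in 1 of 17 (Nrg 89.5, -1.04, adjusted p = 0.95). The replicates' strongest regions gave unequal shares for some of these lists, with 0% and 23.5% for epidermis and cuticle genes and 13.3% and 33.3% for glial genes. These lists are short, and with the 1 kb window the interval of each log2 odds ratio reached below and above 0. With the nearest TSS at any distance the log2 odds ratios turned above 0 for Hox (1.23), segmentation (1.03), mesoderm (1.03), dorsoventral (1.49), glial (1.26), tracheal (0.77), hemocyte (0.77), muscle structural (0.42) and neural fate genes (0.11). That of endoderm and gut genes rose to 1.68 and fell to -0.48 with gene length and number of TSSs in a logistic model, where that of neuronal differentiation genes was -3.49, and no list in this group passed its test under any alternative run on reproducible peaks or on 1 replicate (lowest adjusted p = 0.104, for dorsoventral genes, by Fisher's exact test).

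**Figure D2:**
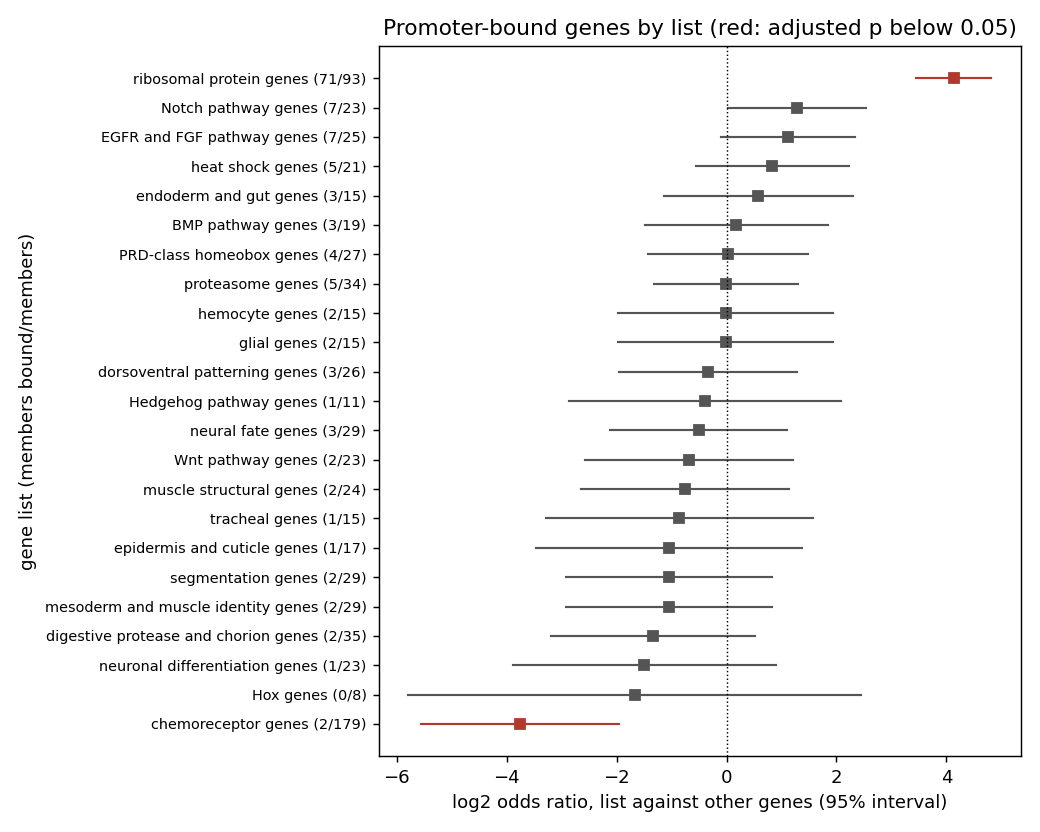
Log2 odds ratio that a gene has a reproducible summit within 1 kb of a TSS (x axis, squares, with 95% intervals as lines), for each of 23 gene lists (y axis, with members bound and members). Ribosomal protein genes (71 of 93) and chemoreceptor genes (2 of 179), in red, have an adjusted p below 0.05.

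The promoter element DRE (TATCGATA), the site of the DNA replication-related element factor DREF, was the fixed motif most concentrated at summits. It occurred within 100 bp of 147 summits (6.04%) against 19 of the same peaks' flanks centred 500 bp away (0.78%, log2 odds ratio 2.99, 95% interval 2.29 to 3.68, exact McNemar test with Benjamini-Hochberg adjustment over 16 motifs, adjusted p = 6.8e-25). All but 1 of these summits were promoter summits, of which 9.04% had the motif. Ohler motif 1 (GGTCACACT), another element of Drosophila core promoters, occurred at 58 summits (2.38%) against 18 flanks (0.74%, log2 odds ratio 1.66, exact McNemar test, adjusted p = 2.5e-05). Against lower-ranked candidates of the same GC content DRE was still more frequent (log2 odds ratio 1.49, Fisher exact test, adjusted p = 2.4e-10), and Ohler motif 1 did not pass the test (0.47, adjusted p = 0.31, from 2.44e-10 to 1 over 9 alternatives). The Ohler motif 1 call was also lost in the more strongly bound peaks (1.40, exact McNemar test, adjusted p = 0.086) and at distal peaks (0.00, adjusted p = 1). Neither the flanks nor the GC-matched candidates were matched for promoter position. Reproducible summits lay at promoters more often than all lower-ranked ones (66.4% against 33.6%). For these 2 promoter elements, the values therefore do not tell a preference for the motif from the preference for promoters. The CA repeat was rarer at summits than in flanks (log2 odds ratio -0.96, exact McNemar test, adjusted p = 7.0e-07), a call that was lost in replicate 2 alone (-0.34, adjusted p = 0.27, from 9.76e-06 to 0.271 over 9 alternatives).

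The homeodomain core TAATTA, the kind of site bound by paired-like homeodomains, was no more frequent at summits than beside them. It occurred at 274 summits (11.3%) and in 288 flanks (11.8%, log2 odds ratio -0.08, 95% interval -0.34 to 0.17, exact McNemar test, adjusted p = 0.79). The paired-class dimer sites P2 (25 summits, log2 odds ratio -0.54, adjusted p = 0.51) and P3 (37 summits, 0.21, adjusted p = 0.79) and the bicoid-type site (154 summits, -0.27, adjusted p = 0.41) did not pass the exact McNemar test either, although within 200 bp the bicoid-type site was rarer than in flanks (269 against 343, -0.39, adjusted p = 0.0069, up to 1 over 9 alternatives). Against all lower-ranked candidates TAATTA was more frequent (log2 odds ratio 0.71, Fisher exact test, adjusted p = 6.1e-11, up to 1 over 9 alternatives), but those regions were richer in GC (48.6% against 39.5%). Against candidates of the same GC content its log2 odds ratio was -0.31 (95% interval -0.55 to -0.06, Fisher exact p = 0.017, adjusted p = 0.067). P3 and the bicoid-type site also passed against all lower-ranked candidates (0.85 and 0.33, Fisher exact test, adjusted p = 0.0064 and 0.02, up to 1) and did not with GC matching (-0.32 and 0.11, adjusted p = 0.5 and 0.57). The remaining motifs, namely GAGA, Zelda, both E-boxes, TATA, GATA, Pho, T-box and Tcf, had log2 odds ratios from -0.25 to 0.27 against flanks and adjusted p from 0.51 to 0.83 by the exact McNemar test. Against all lower-ranked candidates TATA was more frequent (0.82, Fisher exact test, adjusted p = 0.0079, up to 1 over 9 alternatives) and Zelda rarer (-0.85, adjusted p = 0.0091, up to 1), and neither passed with GC matching (-0.22 and -0.48, adjusted p = 0.57 and 0.45). GAGA did pass with GC matching (0.82, Fisher exact test, adjusted p = 0.0011, up to 1). At promoter peaks alone the E-box CAGCTG was more frequent than in flanks (0.51, adjusted p = 0.0066), and at distal peaks alone rarer (-0.83, adjusted p = 0.037), by the exact McNemar test, with adjusted p from 0.00425 to 1 over 9 alternatives.

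**Figure D3:**
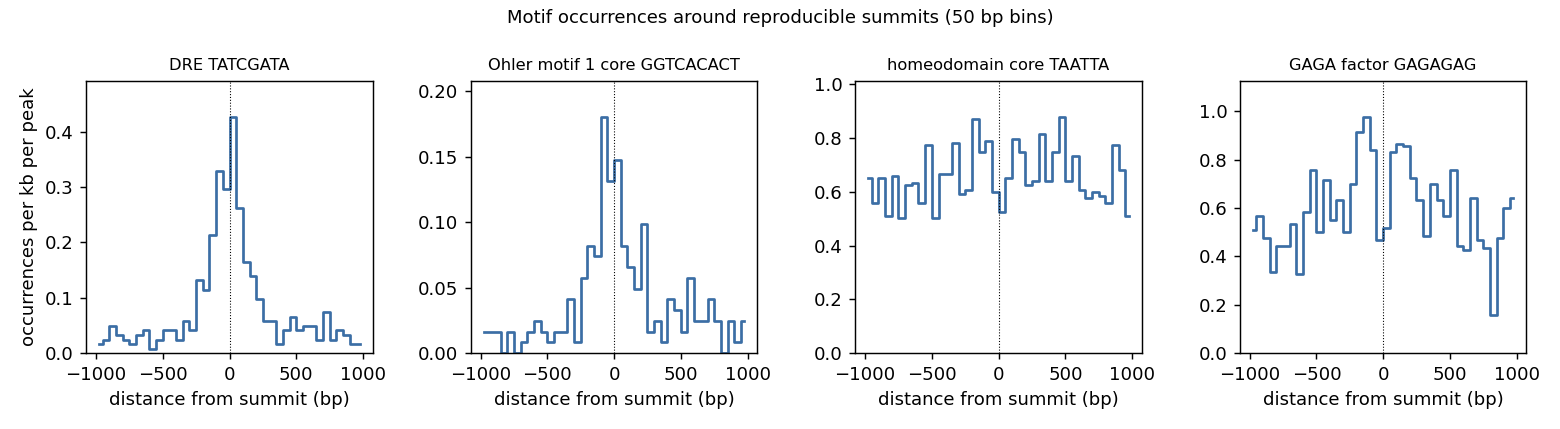
Occurrences per kb per peak (y axis, each panel with its own scale) by distance from the summit in bp (x axis, 50 bp bins) over the 2433 reproducible peaks, for DRE, Ohler motif 1, the homeodomain core and the GAGA site. DRE and Ohler motif 1 rise at the summit, where 6.04% and 2.38% of summits hold them within 100 bp, and the homeodomain core does not.

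Without a fixed list of motifs, 689 of 2080 6-mers were more frequent at reproducible summits than at lower-ranked candidates, and 919 were rarer. The leading ones were rich in A and T, with AAAATA (log2 odds ratio 1.75, Fisher exact test, adjusted p = 6.8e-164), TTTAAA (1.70) and TTAAAA (1.68) first and ATTTTA, AAATAA, TAAAAA, TAAATA and ATTTAA among the first 10. The others were TATCGA (1.56) and CGATAG, which overlap the DRE. With candidates of the same GC content 107 6-mers were more frequent and 85 rarer, and 5 of those first 10 were still more frequent. The leading ones by odds ratio were GGTACC (1.34), CGATAG (1.04), CACTAG (1.01), ACCCTG (0.96) and CGATAC (0.96). GGTACC was rare, at 36 summits against 14 candidates (Fisher exact test, adjusted p = 0.036). CGATAG was at 360 summits against 189 candidates (Fisher exact test, adjusted p = 1.8e-11).

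No preference for transfer RNA genes, which are strongly transcribed, was detected. There were 4 reproducible summits within 250 bp of a tRNA gene, against 2.55 by random placement (permutation p = 0.51) and 28 of the 27267 lower-ranked summits (log2 odds ratio 0.82, 95% interval -0.61 to 2.26, Fisher exact p = 0.33).

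The CG9876 gene itself (FBgn0034821, 2R 23090100 to 23094266, minus strand) had 1 reproducible peak within 5 kb. It lay upstream of the gene, between genes, from 23096986 to 23097355, with its summit at 23097171 and a signal of 88.4, rank 2313 of 2433 (q-value 0.0015). Replicate 1 had a region there with a signal of 49.6, rank 1892 of 30000. No region of replicate 2 was listed there, and of its 2 regions in the window both were near CG9877. That does not show that replicate 2 had no signal at the peak, since signal outside listed regions was not measured here. The CG9876 promoter was not among the bound ones: the combined list had a candidate with its summit at 23094920 and a signal of 49.7 (q-value 0.21), below the weakest reproducible peak.

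**Figure D4:**
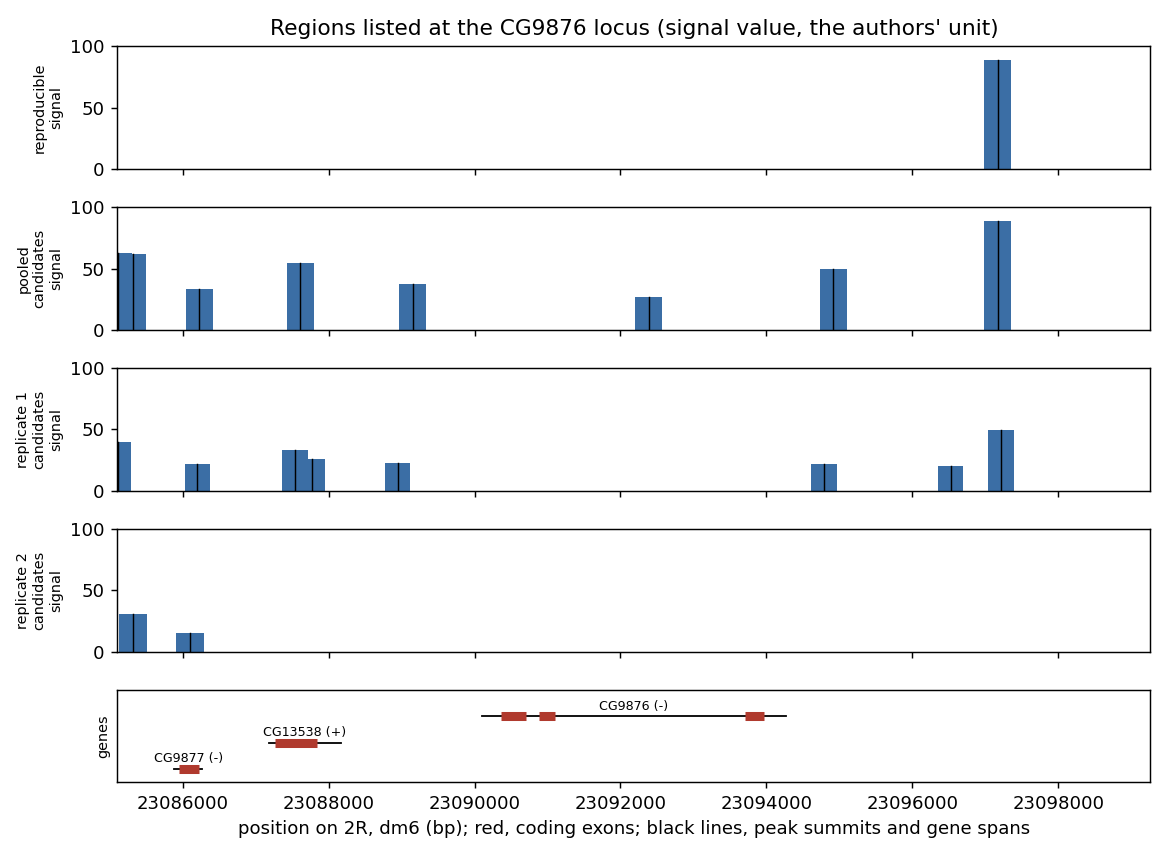
Signal value (y axis) of the regions listed within 5 kb of CG9876 on 2R (x axis, dm6 position in bp), in the reproducible list, the combined candidates and the candidates of each replicate, with summits as black lines and genes with their coding exons (red) at the bottom. The reproducible peak at 23097171 has a signal of 88.4, and replicate 2 has no listed region there.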

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

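The tests of the dm3 sequences and of the 10000 strongest regions of each list were chosen after their results were seen, and the 7 further housekeeping lists after the ribosomal protein result. The heterochromatic and unplaced sequences of dm3 held candidate regions in the replicate lists and in the combined one: 296 of 30000 in replicate 1, 74 in replicate 2 and 137 combined. These sequences lie outside the 6 arms as named in dm3, and under these names they enter only the dm3 lists above. Coordinates were not converted, so whether the dm6 arms, and with them the dm6 results above, hold the same sequence was not checked. Without control libraries the regions were not tested against a background. They were most frequent on 3LHet (98 and 27 regions in the replicates), 2RHet (85 and 11) and 3RHet (64 and 14), and 3 were reproducible. Over these sequences together replicate 1 had 4 times as many as replicate 2 (95% interval 3.09 to 5.23, Fisher exact p = 9.7e-33), while XHet (6 and 11) and Uextra (2 and 4) had fewer in replicate 1.

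Chromosome 4, which is rich in heterochromatin, differed between the replicates the other way, with 29 candidates in replicate 1 and 238 in replicate 2 (ratio 8.21, 95% interval 5.57 to 12.5). A difference in GC content between the lists (means of 48.6% and 46.0%) does not account for the ratio, since it was 6.53 after the same number of regions was drawn per GC bin (95% bootstrap interval 4.55 to 10.02). Regions ranked beyond 10000 do not account for it either, since it was 5.29 among the 10000 strongest (2.96 to 10.1). Among the 2433 strongest, with 6 and 12 regions, the ratio was 2.00 (0.69 to 6.49), so whether the difference extends to the strongest regions, or is held by weaker ones, cannot be told apart with so few. At least 1 strong chromosome 4 site was missing from the replicate 1 list, named here after its values were seen. The summit at RpS3A (combined signal 241.9, rank 345) lay in a region of replicate 2 (117.4) and in no listed region of replicate 1. That 1 peak does not settle the question. Both replicates belong to 1 group, so no biological explanation was tested, and a difference between the libraries may remain.

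The second pattern is the position of the peaks, at promoters and without more homeodomain sites. Binding through the homeodomain core was predicted to make TAATTA more frequent at summits than in their flanks and at candidates of like GC content. Neither was seen. Its log2 odds ratio was -0.08 against flanks (95% interval -0.34 to 0.17) and -0.31 against those candidates (-0.55 to -0.06). Against flanks it was 0.22 at promoter peaks and -0.39 at distal ones, and neither passed the test. The candidates were not matched for promoter position and may hold sites of the same protein, so they cannot decide the question. The flanks show no concentration of TAATTA at summits over the list as a whole, which leaves single peaks open. The ribosomal protein list is 1 gene family, and no preference for tRNA genes was detected (4 summits against 2.55 by random placement, permutation p = 0.51). Promoters of highly transcribed genes in general remain a candidate explanation, since the ribosomal protein list had a log2 odds ratio of 4.13, though no expression data were used here. Housekeeping promoters in general remain one too, since the 7 further lists together were bound in 66 of 291 cases against 15.2% of other genes (log2 odds ratio 0.72, 95% interval 0.32 to 1.12, Fisher exact p = 9.5e-04, and 0.74 without genes near a ribosomal protein gene), while the proteasome and respiratory chain lists had log2 odds ratios of -0.01, with intervals (-1.32 to 1.31 and -0.85 to 0.83) that leave a shift either way open. The 7 lists were not adjusted for gene length, number of TSSs or promoters shared with genes other than ribosomal protein genes. Without genes near a ribosomal protein gene, no single list of the 7 passed the Fisher exact test (lowest adjusted p = 0.067, for translation initiation factors). Neither explanation tells recovery of the tagged protein from recovery of open promoters by any antibody, which the control libraries, not analysed here, would bear on.

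The third question concerns the candidates around CG9876, where extra copies of the locus on the transgene would add DNA and were predicted to raise the number of candidates. Within 20 kb of the gene there were 16 combined candidates, against a median of 14 and a 95th percentile of 25 around the 2852 genes of 2R. The count was not above that percentile, though its Poisson interval, 9.15 to 25.98, reaches above it. A count of listed regions does not measure the amount of DNA, and the control libraries were not analysed. It can therefore neither show nor exclude extra copies, and no biological explanation was tested. Replicate 1 had 18 candidates there, against a median of 13, and replicate 2 had 8, against a median of 15.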

How the results depend on the processing

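The protease and chorion list without Cp190 and Cp110, the 7 further housekeeping lists with their alternative, and the 6-mer background of equal number were chosen after the data were seen. Depth is unknown and there is 1 group, so no result rests on a comparison of conditions, and no IDR value per peak was used, so a list at IDR 0.01 was not run. No paired analysis was possible because there is 1 group. The share of promoter summits (57.7% to 75.5%), and its log2 odds against candidates kept their direction and side of the threshold under each alternative run. The tRNA result passed the test under none, and its direction turned with a 100 bp window (0 summits against 1.45 by random placement). Of 438 alternatives, 392 kept the call, kept a value within its interval over peaks, or kept a count within 1.5 times. That interval is not a spread between replicates. Results without a call in either setting were counted as kept, and a direction was compared only where a value passed its test. Most of the 392, namely 344, concerned single classes, lists and motifs. For the main results, 48 alternatives were kept, 15 moved, 2 were weaker, 1 was stronger and 1 was reversed. Among single classes, lists and motifs, 12 calls were lost and 15 gained, and in 8 of these the direction turned. Where no cause is given, the cause was not tested.

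The stricter list has 1216 peaks by construction. The share of top regions in common was 74.2% for the first 500, 73.2% for 1000, 57.4% for 5000 and 45.8% for 10000, 62.7% with 50% reciprocal overlap and 63.8% with summits within 100 bp. The rank correlation without the top 5% was 0.49. Against next-ranked candidates 3 classes differed, in place of 6, and the log2 odds of X were 0.072. With 1 replicate left out, the promoter minus distal signal was 0.48 to 9.99, and the share on X 16.1% to 19.6%, on opposite sides of its share of length.

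The number of enriched gene lists, 1, was 3 with the nearest TSS, and 0 among lowest-ranked candidates (1 list at an unadjusted Fisher exact p under 0.05). It was also 1 among next-ranked candidates, but there the list was Wnt (8 of 23, log2 odds 2.06, Fisher exact adjusted p = 0.038). Both sets leave out by construction the reproducible peaks, which bound 71 of the 93 ribosomal protein genes. The Hox list could not be fitted in the logistic model. The number of enriched motifs, 2, was 7 against lower-ranked candidates, 1 in the stricter list, and 0 at distal peaks (0 also at an unadjusted exact McNemar p under 0.05). More frequent 6-mers, 689, numbered 107 with GC matching, which also lowers the candidates from 27267 to 2433, and 593 with 2433 candidates of any GC content.

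Against lower-ranked candidates, the log2 odds turned to 0.71 for TAATTA, 0.33 for the bicoid-type site, 0.37 for GAGA and -0.31 for CAGCTG. GAGA also turned to 0.39 with a 200 bp window and 0.82 with GC matching, while at 50 bp it was -0.82. At distal peaks DRE turned to -1.58, from 1 summit, and CAGCTG to -0.83.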

Other observations

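The tests of diverging gene pairs, of further housekeeping groups and of X by rank were chosen after the data were seen. Of the 1615 promoter summits, 693 (42.9%, 95% Clopper-Pearson interval 40.5 to 45.4) had the TSSs of a diverging gene pair within 1 kb, and the strongest regions of the replicates gave 42.2% ± 3.27 (SD, n = 2). Of all lower-ranked summits 8.21% lay within 100 bp of a TSS, against 33.2% of all reproducible ones, and the sets were not matched for this distance. The share with a diverging pair was 20.8% among lower-ranked promoter candidates (log2 odds ratio 1.52, Fisher exact p = 4.2e-74) and 30.2% among the next-ranked (0.79, Fisher exact p = 2.1e-12). Several of the strongest peaks were shared in this way. The X peak at Ugalt (2703716 to 2704055, signal 1375.8) was also the promoter peak of eIF2Bbeta, a translation initiation factor gene. The 2L peak at CenG1A (13835314 to 13835602, 842.7) was also that of mRpS23, and the 3R peak at Art3 (15229382 to 15229684, 830.1) that of mRpS10, both genes of the mitochondrial ribosome.

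Further housekeeping groups were bound at unequal shares. Translation initiation factor genes were bound in 14 of 44 cases (31.8%, log2 odds ratio 1.35, Fisher exact test adjusted over 7 lists, adjusted p = 0.046, replicate mean 29.5% ± 3.21, SD, n = 2), with eIF6 (764) and eIF1 (349.8) after eIF2Bbeta. The eIF1 peak (3L 3222907 to 3223113) was also the promoter peak of RpL28. Without genes that have a TSS within 2 kb of that of a ribosomal protein gene, which left out eIF1, 13 of 43 were bound and the call was lost (log2 odds ratio 1.32, 95% interval 0.40 to 2.25, Fisher exact test, adjusted p = 0.067). V-ATPase genes were bound in 10 of 33 cases (log2 odds ratio 1.26, Fisher exact test, adjusted p = 0.11), RNA polymerase II genes in 4 of 13 (1.34, adjusted p = 0.24), mitochondrial ribosome genes in 17 of 73 (0.73, adjusted p = 0.24) and aminoacyl-tRNA synthetase genes in 7 of 33 (0.60, adjusted p = 0.48). The strongest regions of replicates 1 and 2 bound 30.8% and 15.4% of the RNA polymerase II genes. Respiratory chain genes were bound in 13 of 85 cases (15.3%, log2 odds ratio -0.01, 95% interval -0.85 to 0.83, Fisher exact test, adjusted p = 1), and Sm and LSm genes in 1 of 10 (-0.25, adjusted p = 1).

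The GAGA site was rarer than in flanks within 50 bp of reproducible summits (log2 odds ratio -0.82, exact McNemar test, adjusted p = 0.014) and more frequent within 200 bp (0.39, adjusted p = 0.015, from 0.00115 to 1 over 9 alternatives). Among the candidates ranked 2434 to 30000, X carried more regions of replicate 2 than of replicate 1 in each part of the list, with 1112 against 942 up to rank 10000, 1543 against 1330 up to 20000 and 1734 against 1539 beyond (Fisher exact p = 6.0e-05, 1.9e-05 and 2.1e-04), the opposite of the 2433 strongest.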
